A study of Mus musculus with 6 samples.

How the data were processed

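Bulk RNA was sequenced from bone marrow-derived macrophages of wild-type C57BL/6 mice, which are macrophages grown from marrow precursors in conditioned medium. Per the labels' protocols, the cells were cultured for 7 days and then kept for 24 hours with or without oxidised low-density lipoprotein (oxLDL, a modified lipoprotein that macrophages take up through scavenger receptors) at 50 µg/ml. The 6 samples formed 2 groups of 3, oxLDL-treated and untreated, and each group held the numbers 1, 2 and 3. Groups and numbers were taken from the sample titles. Poly(A) RNA was selected and a stranded kit was used, per the labels' protocols, while the strand setting of the counting was not given in the sources used here.

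The authors deposited 2 tables of 24054 genes. The first held expected counts estimated with RSEM, per the file's name and the submitters' processing notes, which list Bowtie2 2.1.0, RSEM 1.2.15 and edgeR without a version. Between 10.4% and 11.1% of the expected counts of a sample were not whole (tolerance 0.005), because RSEM divides reads that map to several genes. These values were rounded to whole numbers before any count test. The second deposited table held a normalised signal, CPM of a library size that the authors scaled with TMM factors, per the file's name. Its columns were whole reads times a constant: 100% of the recovered values were whole within 0.005, and at least 99.9% of them equalled the rounded expected counts. The submitters' processing notes list hg19, a human build, although the samples were mouse and the tables carried mouse symbols. For that reason no coordinates are given. The annotation behind the counts was not given in the sources used here.

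Totals ran from 13546572 to 15559310 expected counts per sample, and the precursor ribosomal RNA gene Rn45s took 0.99% to 1.51% of them. Genes were kept with the defaults of filterByExpr (minimum count 10, minimum total count 15), which left 11400 genes for testing. Libraries were scaled with TMM factors between 0.942 and 1.06. The main test was the quasi-likelihood test of edgeR 4.0.16 with robust estimation, run in R 4.3.3 with group as the only term, and Benjamini-Hochberg adjusted p-values below 0.05 counted as past the threshold. Fold changes are oxLDL over untreated on the log2 scale, with the standard error (SE) derived from the fold change and its F statistic. Levels are TMM-scaled CPM, as mean ± SD over the 3 samples of a group. Nothing in the labels says that the replicates were separate cultures or animals, so p-values measure only the spread between these samples, part of which may be technical.

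The labels give both groups the same 3 numbers without saying what a number marks. Every sample title also carries the word mix, which the labels do not explain. Deviations of log2 CPM from the group means were correlated between same-numbered samples at r = 0.66, 0.45 and 0.70 across genes, each above the limit of 0.1 set for pairing. Unlike numbers also correlated: untreated sample 2 with oxLDL sample 1 at r = 0.63, above the value of pair 2, and untreated sample 1 with oxLDL sample 2 at 0.20. The other 4 combinations of unlike numbers were negative (-0.76 to -0.37), so pairs 1 and 2 were parted from pair 3 more clearly than from each other. By the limit for same numbers they were still taken to pair the samples, a decision made before the calls of the fits were compared. Xist, an RNA of the inactive X chromosome, was closest between same-numbered samples. It measured 957, 505 and 0.341 CPM in untreated samples 1, 2 and 3 and 966, 346 and 0.0724 CPM in the oxLDL samples. The sum of 4 Y-linked genes parted pair 1 (64.6 and 59.1 CPM) from pairs 2 (228 and 221) and 3 (230 and 265). The numbers were therefore not repeat libraries of a single pool of cells. The fit with the replicate number as a block is given beside the fit without it wherever it changed a call. It was fitted with the same tool, filter and threshold. The fit without the block was the planned main fit. The choice to lead with the blocked fit and to describe single genes from it was made after the call counts of both fits, 0 and 672, had been seen.

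Before the data were examined, 24 lists of genes of macrophage state and 9 lists of markers of other cell types were fixed. Lists with at least 3 measured members, 28 in all, were tested with camera of limma 3.58.1 on log2 CPM values (prior count 2), with a preset inter-gene correlation of 0.01. Camera compares the members with the remaining genes. Camera with a correlation estimated from the data was run beside it, as was fry, which asks whether the members of a list moved on balance in a direction. The tests were adjusted over the 28 lists. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone. Median log2 fold changes of a list are those without the block unless stated. Symbols were matched as written, so Adgre1, present under its older symbol Emr1, and Lilrb4a were not matched to the table.

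The genes to be named were also fixed by rule. Part (a) took the 5 largest rises and the 5 largest falls among genes past the threshold with a mean log2 CPM of at least 3 and groups that did not overlap. Part (b) took the 2 members with the smallest unadjusted p in each list of macrophage state, and these may be left out for a list whose test and members all missed the threshold. Part (c) took Cd36, Hmox1, Abca1, Itgam, Itgb2, Itgb1, Fermt3 and Tln1 whatever their result. Part (d) took the marker with the highest mean CPM in each marker list. Part (a) found 0 genes without the block. It was applied to the blocked fit after the data had been seen, where 346 genes qualified. All further genes named in the text, such as Ccl2 and Scarb1, were chosen after their values were seen.

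The procedure was tested on simulated counts for the comparison of oxLDL with untreated samples, with 200 changed genes among 11272 tested. Without the block edgeR recovered 1% of the 100 genes changed by a log2 fold of 1 and 45% of the 100 changed by a log2 fold of 2, with 0 false calls. With the block it recovered 53% and 98%, with 16 false calls among 167. DESeq2 1.42.0 with the block made 37 false calls among 201. The alternatives tried were other scalings, filters, tests and thresholds, the authors' normalised table, the replicate block, each sample left out, each numbered pair left out and a correction for GC content and gene length. A check of replicates found no library deposited more than once: the chi-square per degree of freedom between replicates was at least 29.8.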

Results

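The transcriptomes of 3 oxLDL-treated and 3 untreated samples of mouse bone marrow-derived macrophages were measured by bulk RNA sequencing after 24 hours. Totals were 15559310, 14447811 and 14814244 expected counts in untreated samples 1, 2 and 3, and 14433169, 14160443 and 13546572 in the oxLDL samples of the same numbers. In log2 CPM, untreated samples 1 and 2 correlated at r = 0.984 across genes, and untreated sample 3 correlated with them at 0.889 and 0.897. Among oxLDL samples these values were 0.983, 0.908 and 0.922. The first principal component held 56.7% of the variance and the second 31.3%. The libraries numbered 3 stood apart from the others of their own group, and each numbered pair shifted in the same direction on both components with oxLDL.

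**Figure D1:**
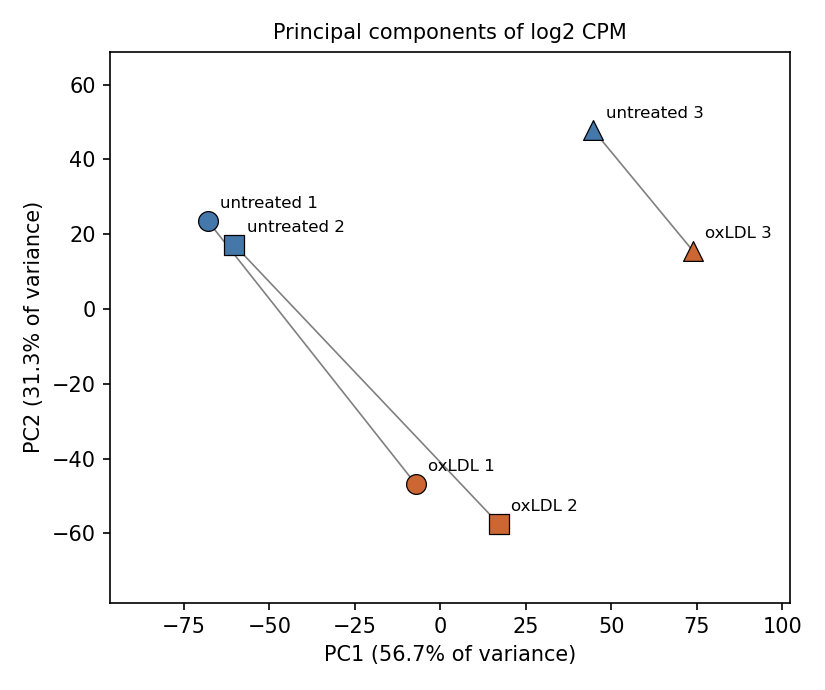
Principal components of log2 CPM for the 6 libraries. The x axis is the first component (56.7% of variance) and the y axis the second (31.3%), in log2 units. Each point is a library (blue untreated, orange oxLDL, with circles, squares and triangles for the numbers 1, 2 and 3), and grey lines join libraries of the same number. Along the first component the libraries numbered 3 lie highest (44.8 untreated and 73.8 oxLDL). The oxLDL samples 1 and 2 (-7.24 and 17.1) lie between them and untreated samples 1 and 2 (-68.1 and -60.4).

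The comparison of treated with untreated cells asked which transcripts of macrophages differ after exposure to oxLDL. Genes of antioxidant defence were higher with oxLDL, among them Slc7a11, the cystine transporter that feeds glutathione synthesis, which rose from 54.3 ± 76.7 to 484 ± 360 CPM (SD, n = 3 per group). Interferon-stimulated genes were lower, among them the antiviral GTPase Mx1, which fell from 132 ± 32.1 to 5.67 ± 3.78 CPM. Monocyte chemokines, enzymes of sterol synthesis, regulators of integrins and actin, and macrophage identity genes were also lower as groups. These group calls were made with a preset correlation between genes, and with a correlation estimated from the data 0 of 28 lists passed (smallest adjusted p = 0.416, and 0.628 with the block). With the replicate number as a block, edgeR's quasi-likelihood test found 672 genes past an adjusted p of 0.05, of which 218 rose and 454 fell with oxLDL. The words "rose", "fell" and "did not pass" of a single gene refer to this fit throughout.

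Without the block, 0 of 11400 genes passed in edgeR (smallest adjusted p = 0.0667), while 1674 had an unadjusted p under 0.05, DESeq2 called 872 and limma-voom 10. The count depended on the libraries numbered 3: without the block it was 737 without untreated sample 3 and 31 without oxLDL sample 3, and with the block it was 0 without pair 1, 0 without pair 2 and 3446 without pair 3. The oxLDL and untreated samples did not overlap in 437 of the 672 genes, and in 21.1% of all tested genes. Chance would give 10% if the 6 samples were exchangeable, which their pairing makes doubtful. Median log2 ratios of the genes that rose were 1.31, 1.31 and 0.97 in pairs 1, 2 and 3, and those of the genes that fell were -1.48, -1.76 and -1.26. The blocked fit favours genes with like ratios in all pairs, and all 672 had the same direction in all 3. Over all tested genes the log2 ratios correlated at r = 0.86 between pairs 1 and 2. They correlated at 0.49 between pairs 1 and 3 and at 0.55 between pairs 2 and 3. Ratios went beyond 2-fold in 16.7%, 18.9% and 9.1% of genes in pairs 1, 2 and 3. Whether the response differed between pairs was not tested, because each pair held a single library per group.

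Among genes with a mean log2 CPM of at least 3 and groups that did not overlap, the largest rises with the block were those of Slc7a11, Clec4n, Vegfa, Stac2 and Ifi27. The log2 fold change of Slc7a11 was 4.07 ± 0.56 with the block (SE; edgeR adjusted p = 0.0362) and 3.15 ± 1.28 without it (adjusted p = 0.336), with log2 ratios of 4.82, 4.72 and 2.65 in pairs 1, 2 and 3. Its counts were not whole in 6 samples, so some of its reads were shared with other genes. Clec4n, the fungal pattern receptor Dectin-2, rose from 15.4 ± 3.35 to 147 ± 83.2 CPM (SD, n = 3), a log2 fold change of 3.06 ± 0.32. Vegfa, an angiogenic growth factor, rose by 2.92 ± 0.41 (adjusted p = 0.0369, edgeR), Stac2 by 2.71 ± 0.23 (adjusted p = 0.0286, edgeR) and Ifi27 by 2.29 ± 0.22 on the log2 scale. Among the same genes the largest falls were those of I830012O16Rik (-5.11 ± 0.82), the interferon-inducible GTPase Iigp1 (-5.10 ± 0.85), Aif1 (-4.82 ± 0.71), Mx1 (-4.67 ± 0.40) and Slamf9 (-4.62 ± 0.47). Aif1 encodes an actin-binding protein of macrophages and went from 142 ± 94.9 to 4.67 ± 3.92 CPM. I830012O16Rik also had counts that were not whole in 6 samples.

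Of the 28 lists tested with camera, 16 passed the threshold with the preset correlation, 4 of them higher and 12 lower with oxLDL, and the same number passed with the block. With an estimated correlation 0 lists passed (smallest adjusted p = 0.416), and fry passed 4 lists without the block and 0 with it (smallest adjusted p = 0.123). Each list call below is therefore a call with the preset correlation. Other splits of the 6 samples into 3 and 3 passed 5 to 14 lists in that test without the block. Over all genes tested, 0 members of any list passed in edgeR without the block, so counts of members that rose, fell or passed are those of edgeR's blocked fit. DESeq2 with the block called at least as many members of every list.

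The NRF2 list, genes of antioxidant defence and detoxification, was higher with oxLDL (camera adjusted p = 5.13e-13; adjusted p = 0.416 with an estimated correlation). Of 26 measured members, 8 rose, 0 fell and 18 did not pass. The number that rose was 21 with the block and 12 without it when adjusted over the list alone. The median log2 fold change of the list was 1.27, with medians of 1.47, 1.75 and 0.80 in pairs 1, 2 and 3, and all 26 members had a positive value. Abcc1, an exporter of glutathione conjugates, rose from 208 ± 18.8 to 559 ± 96.0 CPM (log2 fold change 1.41 ± 0.17, edgeR adjusted p = 0.0309), and the haem transporter Slc48a1 rose from 166 ± 12.8 to 354 ± 27.9 CPM. Hmox1, which breaks down haem, rose by 1.21 ± 0.20 on the log2 scale (edgeR adjusted p = 0.0443 with the block, 0.635 without it). Nqo1, a quinone reductase, rose from 2.25 ± 1.21 to 26.0 ± 11.5 CPM, the glutathione transferase Gsta3 from 1.01 ± 1.04 to 30.4 ± 12.1 CPM, and the peroxiredoxin Prdx6 had a log2 fold change of 1.89 ± 0.18. The metal and iron list did not pass (camera adjusted p = 0.266), but its metallothioneins Mt1 and Mt2 rose by 1.37 ± 0.20 and 1.69 ± 0.24 and the siderophore-binding Lcn2 fell by 2.03 on the log2 scale. With the block, 4 of its 10 measured members rose and 3 fell, adjusted over the list alone. The iron exporter Slc40a1 had a log2 fold change of 2.37 ± 0.59 and did not pass (edgeR adjusted p = 0.0840).

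Genes of lipid handling moved in different directions. The sterol synthesis list, targets of SREBP2, was lower (camera adjusted p = 2.47e-07; adjusted p = 0.477 with an estimated correlation), with a median log2 fold change of -1.08. Of 23 measured members, 4 fell and 0 rose, among them Stard4 (-1.41 ± 0.24), Dhcr7 (-1.22 ± 0.12) and Pmvk (-1.06 ± 0.16). Adjusted over the list alone, 16 fell with the block and 0 without it. Idi1 and Mvk, enzymes of the same pathway, had values of -2.00 ± 0.38 and -1.003 ± 0.19 and did not pass (edgeR adjusted p = 0.0556 and 0.0520). The list of receptors for modified lipoproteins was lower (camera adjusted p = 0.0251; adjusted p = 0.416 with an estimated correlation). Its call ended without oxLDL sample 2 (adjusted p = 0.0658) or oxLDL sample 3 (0.0804). Of its 14 measured members, 1 fell, the HDL receptor Scarb1 (-1.36 ± 0.11), and 5 fell adjusted over the list alone with the block. Cd36, a scavenger receptor for oxLDL, measured 631 ± 152 CPM untreated and 961 ± 417 CPM with oxLDL, a log2 fold change of 0.51 ± 0.28 that did not pass (edgeR adjusted p = 0.291). Marco (-3.43 ± 1.17) did not pass either.

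The list of PPAR targets and fatty acid use was higher (camera adjusted p = 0.0154; adjusted p = 0.493 with an estimated correlation), with 3 of 18 measured members up and 1 down. Acadl, an enzyme of fatty acid oxidation, rose from 75.6 ± 6.44 to 126 ± 22.4 CPM, and the lipid droplet gene Hilpda and the lipase inhibitor Angptl4 rose by 1.83 ± 0.20 and 2.17 ± 0.34 on the log2 scale. Lpl, the secreted lipoprotein lipase, fell (-1.50 ± 0.26). Pnpla2, a lipase of lipid droplets, had a value of 0.60 ± 0.14 and did not pass (edgeR adjusted p = 0.0761). In the blocked fit 6 rose and 2 fell, adjusted over the list alone. The list's call ended without untreated sample 3 (adjusted p = 0.101) or oxLDL sample 2 (0.0658). The list of lipid-associated macrophage genes was higher (camera adjusted p = 0.00557; adjusted p = 0.530 with an estimated correlation), although Lpl, which fell, was the only one of its 17 members past the threshold in edgeR with the block, over all genes or adjusted over the list alone. DESeq2 with the block called 7 of them higher and 1 lower. Its medians in pairs 1, 2 and 3 were 1.19, 0.70 and -0.04, and its call ended with pair 1 left out (adjusted p = 0.0522). Cd9 and Syngr1 had log2 fold changes of 2.06 ± 0.46 and 1.57 ± 0.42 and did not pass.

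LXR targets did not pass as a list (camera adjusted p = 0.682), with 1 of 14 measured members up and 1 down. Arl4c rose (1.06 ± 0.17), and Nr1h3, which encodes the sterol receptor LXR alpha, fell (-1.23 ± 0.20). With the block, 1 rose and 3 fell, adjusted over the list alone. Abca1, the cholesterol exporter, measured 977 ± 226 CPM untreated and 1108 ± 449 CPM with oxLDL, a log2 fold change of 0.12 ± 0.41 that did not pass. Pltp (-1.53 ± 0.37) and Apoc2 (-1.75 ± 0.55) did not pass. The lysosome list did not pass (camera adjusted p = 0.270, and 0.0316 with pair 3 left out). Of its 24 measured members, 1 rose over all genes and adjusted over the list alone, the proton pump subunit Atp6v0d2 (2.18 ± 0.25), and the transcription factor Tfe3 had a value of -0.64 ± 0.14 and did not pass.

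Interferon-stimulated genes had the largest median change of the 28 lists. They were lower with oxLDL (camera adjusted p = 1.06e-20; adjusted p = 0.416 with an estimated correlation), and all 27 measured members had a negative value. With the block 10 fell, 0 rose and 17 did not pass, and adjusted over the list alone 27 fell with the block and 19 without it. The median log2 fold change was -2.44 without the block and -2.99 with it, with medians of -3.28, -4.21 and -1.60 in pairs 1, 2 and 3. Ifi204, a DNA-sensing protein, fell from 466 ± 66.6 to 64.3 ± 12.9 CPM (SD, n = 3), a log2 fold change of -2.87 ± 0.22 (edgeR adjusted p = 0.0284). The transcription factor Stat2 fell from 433 ± 80.7 to 85.7 ± 42.6 CPM, the deconjugating protease Usp18 from 131 ± 54.4 to 25.8 ± 22.5 CPM, and the virus-tethering protein Bst2 from 429 ± 104 to 128 ± 86.9 CPM.

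Chemokine genes were also lower. The list of monocyte chemokines and their receptors was lower (camera adjusted p = 0.0154; adjusted p = 0.440 with an estimated correlation), with 6 of 12 measured members down, 0 up and a median log2 fold change of -1.72. Its call ended without untreated sample 3 (adjusted p = 0.115). In the blocked fit 2 rose and 8 fell, adjusted over the list alone. The fractalkine receptor Cx3cr1 fell from 6.69 ± 2.38 to 1.83 ± 0.045 CPM. The ligands Ccl12 (-5.13 ± 0.37), Ccl7 (-2.79 ± 0.24), Ccl2 (-2.40 ± 0.14) and Ccl8 (-2.35 ± 0.41) fell as well. The list of NF-kB mediators was lower (camera adjusted p = 0.00657; adjusted p = 0.598 with an estimated correlation), with 3 of 17 measured members down: the chemokines Ccl3 (-0.75 ± 0.11) and Ccl4 (-1.32 ± 0.12) and the cytokine signalling inhibitor Socs3 (-1.95 ± 0.22). Members below the count filter were not tested, and 4 of them had more counts in oxLDL sample 3 than in untreated sample 3: Il6 (825 and 239), Il1a (642 and 241), Cxcl3 (336 and 50) and Cxcl1 (182 and 26). Nfkbiz had a value of -3.23 ± 1.21 that did not pass (edgeR adjusted p = 0.169). With the block, 1 rose and 8 fell, adjusted over the list alone. The NF-kB call ended without untreated sample 3 (adjusted p = 0.208), oxLDL sample 1 (0.347) or oxLDL sample 2 (0.318), and with pair 1 left out (0.120).

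The series is about the myeloid adhesome, the integrins and the proteins that couple them to the cytoskeleton. The list of integrin adaptors and signalling proteins was lower (camera adjusted p = 0.00310; adjusted p = 0.477 with an estimated correlation), with 7 of 37 measured members down, 2 up and a median log2 fold change of -0.32. In the blocked fit 2 rose and 12 fell, adjusted over the list alone. Fermt3, which encodes the integrin activator kindlin-3, fell from 369 ± 116 to 190 ± 47.6 CPM, a log2 fold change of -0.93 ± 0.13 (edgeR adjusted p = 0.0371 with the block, 0.263 without it). The Src-family kinase Lyn (-1.73 ± 0.21), the adaptor Fyb (-1.86 ± 0.22), the small GTPase Rap1b (-1.45 ± 0.24), Evl (-0.89 ± 0.16) and Zyx (-0.74 ± 0.13) also fell. Parvb rose from 28.0 ± 3.91 to 55.4 ± 4.61 CPM, and the kinase Src rose by 1.09 ± 0.17 on the log2 scale. Talin, Tln1, measured 985 ± 420 and 756 ± 264 CPM and did not pass (-0.34 ± 0.19, edgeR adjusted p = 0.293).

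Integrin subunits did not pass as a list (camera adjusted p = 0.0882; fry adjusted p = 0.0187 without the block and 0.128 with it). Of 14 measured members, 1 fell over all genes, Itgal, the alpha chain of LFA-1, from 514 ± 348 to 23.9 ± 12.3 CPM (-4.36 ± 0.70, edgeR adjusted p = 0.0449). With the block, 3 rose and 5 fell, adjusted over the list alone. Itgam, the alpha chain of Mac-1, measured 2127 ± 1019.7 CPM untreated and 465 ± 146 CPM with oxLDL, and its log2 fold change of -2.14 ± 0.41 did not pass (adjusted p = 0.0547, edgeR). Its counts were not whole in 6 samples. Itgb3 measured 4.95 ± 3.58 and 94.8 ± 58.9 CPM and did not pass (4.23 ± 0.87, edgeR adjusted p = 0.0629). The shared beta chains Itgb2 (-0.24 ± 0.17) and Itgb1 (-0.13 ± 0.18) did not pass.

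**Figure D2:**
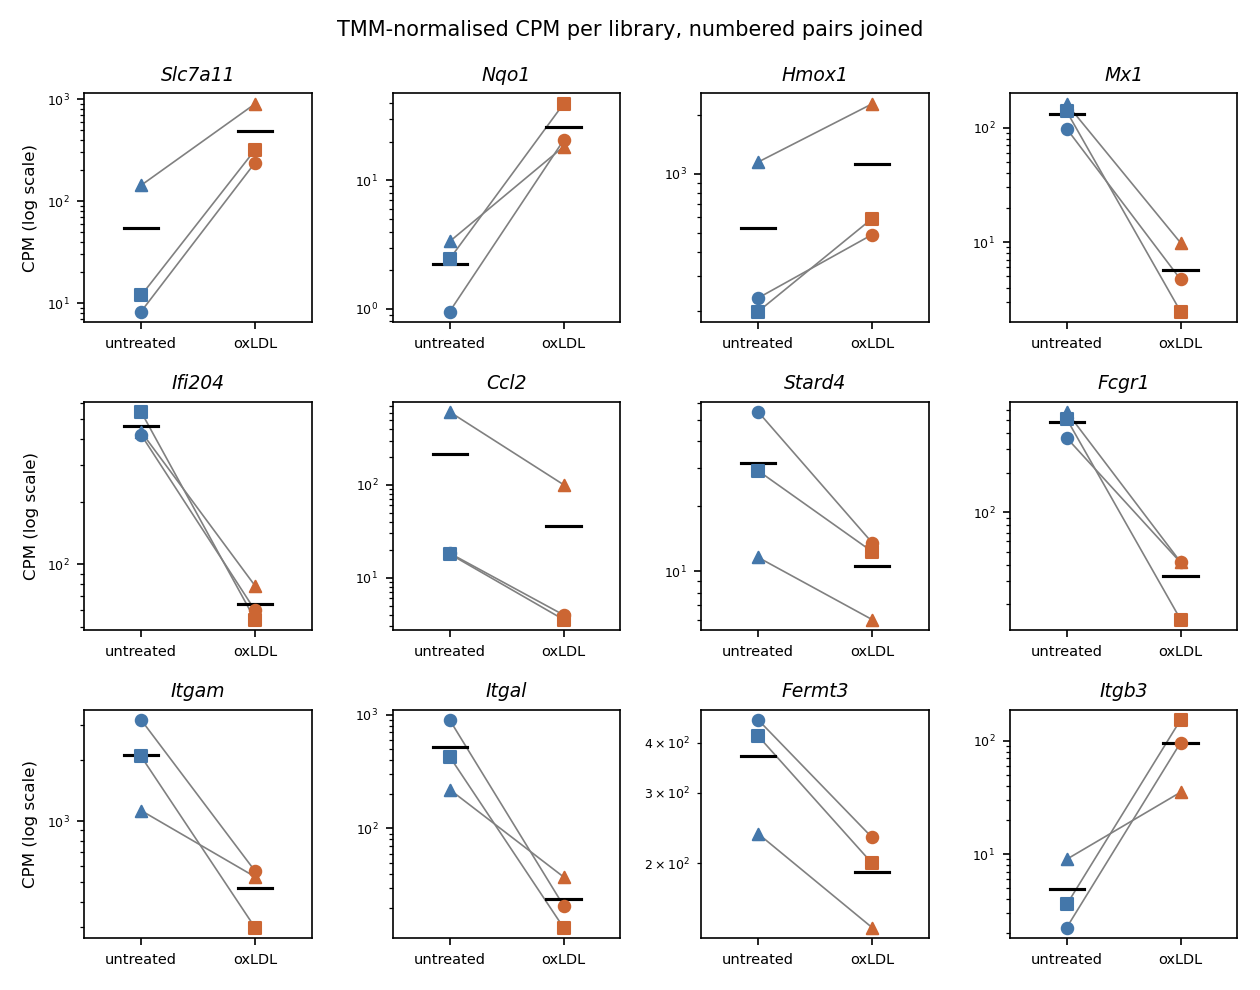
Levels of 12 genes in the 6 libraries. The y axis is TMM-scaled CPM on a log scale and the x axis the group, with blue untreated and orange oxLDL points, circles, squares and triangles for the numbers 1, 2 and 3, grey lines joining libraries of the same number and black bars for the group mean. Slc7a11 was higher with oxLDL in all 3 pairs, and Mx1, Itgal and Fermt3 were lower in all 3.

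Regulators of podosomes and actin were lower as a list (camera adjusted p = 4.20e-06; adjusted p = 0.477 with an estimated correlation), with 4 of 25 measured members down and 0 up. These were Coro1a (-1.67 ± 0.22), Myo1e (-1.25 ± 0.18), Dock2 (-0.999 ± 0.15) and the actin-binding Pfn1 (-0.98 ± 0.17), and Hcls1 had a value of -0.78 ± 0.19 that did not pass. In the blocked fit 1 rose and 17 fell, adjusted over the list alone. Matrix genes and proteases did not pass as a list (camera adjusted p = 0.234, and 0.0371 without untreated sample 3). Of 16 measured members, 2 fell, the collagenase Mmp14 (-1.97 ± 0.19) and Tgfbi (-1.28 ± 0.22). With the block, 4 rose and 3 fell, adjusted over the list alone. Mmp12, macrophage elastase, measured 25.1 ± 17.5 CPM untreated and 816 ± 961 CPM with oxLDL and did not pass (4.68 ± 1.01, edgeR adjusted p = 0.0689), nor did Thbs1 (2.30 ± 0.52).

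Macrophage identity genes were lower as a list (camera adjusted p = 8.92e-05; adjusted p = 0.416 with an estimated correlation), with 3 of 13 measured members down and 0 up. Fcgr1, the high-affinity IgG receptor, fell from 486 ± 108 to 32.9 ± 15.2 CPM (-3.98 ± 0.44), and Spi1, which encodes the lineage factor PU.1, from 375 ± 127 to 169 ± 44.5 CPM (-1.13 ± 0.14). Aif1 was the third. Adjusted over the list alone, 1 rose and 7 fell with the block, and 7 fell without it. Of the marker lists of other cell types, monocyte markers were lower (camera adjusted p = 0.00143; adjusted p = 0.416 with an estimated correlation), with 2 of 6 down, Plac8 (-3.99 ± 0.33) and Hp (-1.61 ± 0.17), and 5 adjusted over the list alone. Ccr2 had a value of -1.98 ± 0.54 and did not pass. Neutrophil markers were lower (camera adjusted p = 0.00310; adjusted p = 0.416 with an estimated correlation), with 1 of 6 down over all genes and over the list alone, the cytokine receptor Csf3r, from 203 ± 44.9 to 90.7 ± 15.2 CPM. The monocyte list shares Ccr2 with the chemokine list and Chil3 with the alternative activation list.

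Osteoclast and dendritic cell markers did not pass in camera (adjusted p = 0.277 and 0.682), while fry passed the osteoclast markers as lower (adjusted p = 0.0413 without the block and 0.128 with it). Of 3 measured osteoclast markers the acid phosphatase Acp5 fell (-2.72 ± 0.34), over the list alone as well, and Nfatc1 did not pass. Of 3 dendritic cell markers 0 passed, and Ccr7 measured 2.88 ± 3.60 and 5.32 ± 5.81 CPM. Lists with fewer than 3 measured members were not tested: Cd79b of the B cell list fell (-1.83 ± 0.26), Cd4 of the T cell list, Kit of the mast cell list and Pf4 of the megakaryocyte list did not pass, and 0 fibroblast markers were above the count filter.

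Among the remaining lists, the chaperones of the endoplasmic reticulum were lower (camera adjusted p = 0.0301; adjusted p = 0.691 with an estimated correlation), with 2 of 18 down. These were Herpud1, from 165 ± 38.9 to 52.9 ± 0.831 CPM (-1.61 ± 0.18), and Pdia4 (-1.08 ± 0.16), and adjusted over the list alone 5 fell with the block. The call ended without untreated sample 3 (adjusted p = 0.690, direction up), oxLDL sample 1 (0.191) or oxLDL sample 2 (0.153), and with pair 3 left out (0.210). The glycolysis and hypoxia list was higher (camera adjusted p = 0.00310; adjusted p = 0.598 with an estimated correlation), with 1 of 24 up and 1 down. Vegfa, a growth factor, rose, and Pfkfb3, which makes an activator of glycolysis, fell (-0.82 ± 0.14). Adjusted over the list alone, 7 rose and 1 fell with the block, and the list's call ended without untreated sample 2 (adjusted p = 0.0738) or oxLDL sample 3 (0.175). Pdk1 (0.58 ± 0.20) and Pfkp (0.57 ± 0.19) did not pass. Cell cycle genes were lower as a list (camera adjusted p = 8.11e-05; adjusted p = 0.598 with an estimated correlation), with medians of -0.52, -1.84 and -0.15 in pairs 1, 2 and 3. Of their 34 measured members 0 passed in edgeR with the block, over all genes or the list alone, while DESeq2 with the block called 8 lower. Those not past the threshold in edgeR included Mcm2 (-0.65 ± 0.19) and Tpx2 (-0.995 ± 0.21).

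The lists of alternative activation (camera adjusted p = 0.993), class II antigen presentation (0.339), the ATF4 stress response (0.384), heat shock (0.729) and oxidative phosphorylation (0.485) did not pass. Alternative activation had a positive median log2 fold change of 0.25 and a negative mean of -0.24, and of its 9 measured members Il10 fell, from 8.93 ± 7.20 to 0.291 ± 0.394 CPM (-5.04 ± 0.49, edgeR adjusted p = 0.0286). Chil3 (-1.94 ± 0.48) did not pass, and adjusted over the list alone 4 rose and 2 fell with the block. In the ATF4 list Nupr1 fell (-0.88 ± 0.13), over the list alone as well, and Shmt2 (0.57 ± 0.16) and Slc7a5 (-0.55 ± 0.26) did not pass. The ATF4 list passed as higher without untreated sample 3 (camera adjusted p = 0.00586) and with pair 3 left out (0.0180), and oxidative phosphorylation passed as higher with pair 1 left out (0.0355). In the class II, heat shock and oxidative phosphorylation lists 0 members passed in edgeR with the block over all genes or over the list alone, while DESeq2 with the block called 1, 1 and 0 lower.

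**Figure D3:**
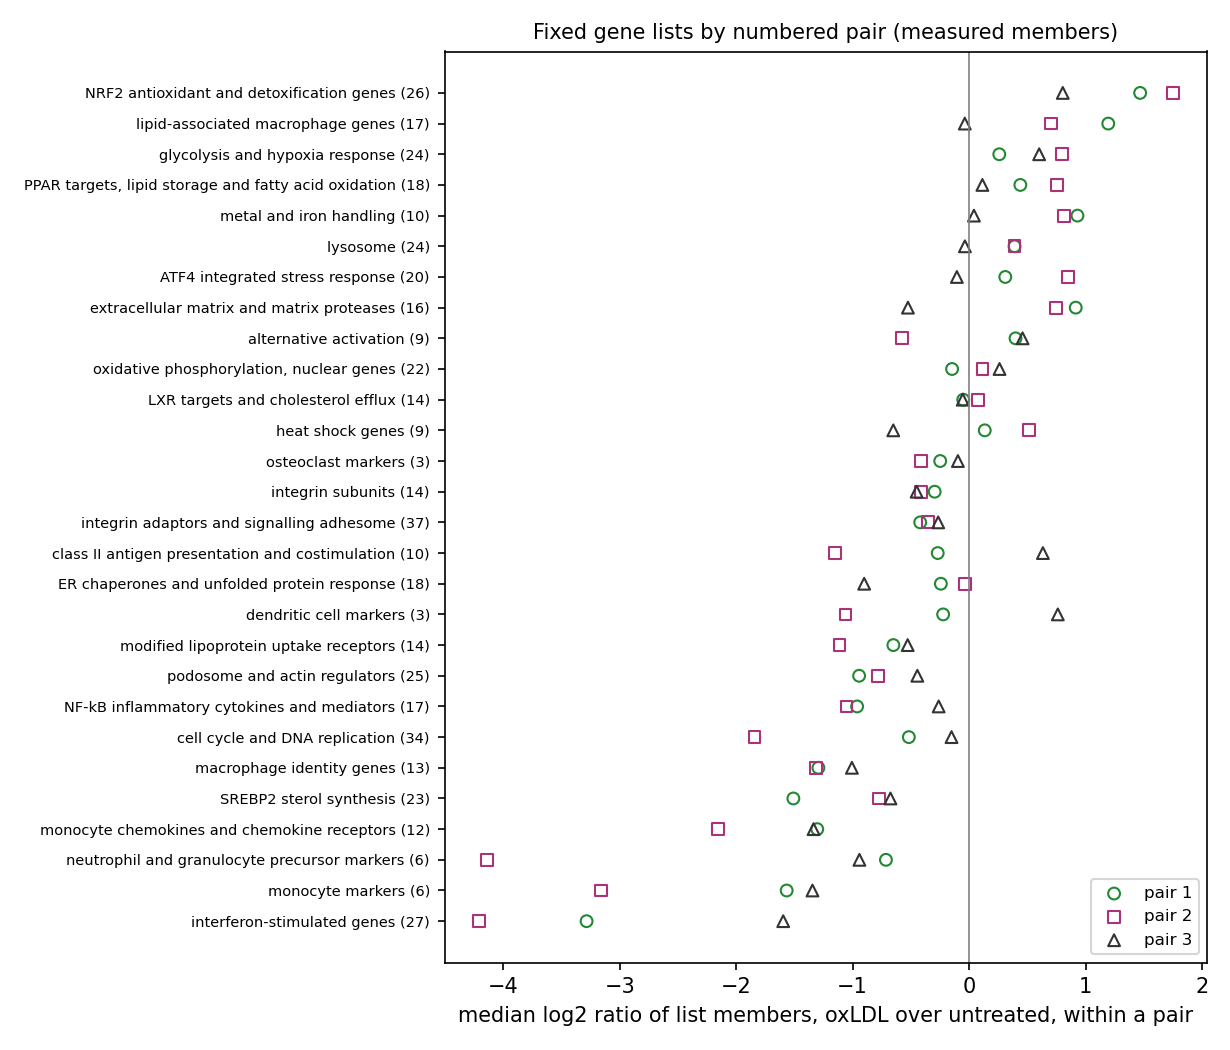
Median log2 ratio of oxLDL over untreated within each numbered pair, for the 28 tested lists. The x axis is the median over the measured members (log2 units) and the y axis the list, with the number of measured members in brackets. Circles, squares and triangles are pairs 1, 2 and 3. Interferon-stimulated genes had medians of -3.28, -4.21 and -1.60 and NRF2 genes of 1.47, 1.75 and 0.80 in pairs 1, 2 and 3.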

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

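The block with another test, scaling, filter or GC correction, the recovered reads, the older symbols and the omission of a numbered pair were chosen after seeing the data; the other alternatives were fixed before. Without the block, edgeR called 0 genes also with RLE or upper-quartile factors, the stricter filter, an adjusted p below 0.01, a test against a fold of 1.5 and the recovered reads. It called 8 without a filter, DESeq2 called 872 and limma-voom 10, and the authors' normalised table gave 36 with a pseudocount of 1 and 12 with 0.1. Leaving out each sample gave 0 to 737, and leaving out pairs 1, 2 and 3 gave 0, 0 and 3132. The replicate block gave 672. Within it, DESeq2 called 1853, and leaving out pairs 1, 2 and 3 left 0, 0 and 3446. The other blocked settings gave 597 to 960 genes. Of the blocked calls 218 were higher and 454 lower, against 249 and 348 with upper-quartile factors and 1618 and 1828 with pair 3 left out. Every omitted pair left as many samples, and the cause of the changes in the counts was not tested. Removing GC content and gene length trends gave 676 calls, of which 638 were among the 667 called before on the same genes. The median log2 difference of all genes was 0.119 with upper-quartile and 0.117 with total-count scaling, and 0.014 with TMM.

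Of the lists, 0 passed with an estimated correlation and 4 with fry. Leaving out each sample gave 12 to 16, leaving out pairs 15, 16 and 17, and the block, RLE factors, the stricter filter and older symbols 16 each. The block changed no call of a list by camera with the preset or the estimated correlation, and it ended the 4 of fry. It brought 70 of the 105 named genes past the threshold, and 35 stayed short of it. Many of the 105 were named for passing in the blocked fit or after their values were seen. The 70 are therefore no check of the block.

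Of 1890 log2 fold changes of named genes under the alternatives, 19 had the opposite sign, 0 of them past the threshold. With each sample left out, the values ran from a lowest without oxLDL sample 3 to a highest without untreated sample 3 for Ccl2 (-5.86 to 0.99), Ccl7 (-6.19 to 0.61), Hp (-4.41 to 1.27), Lcn2 (-7.95 to 3.88), Mmp14 (-5.46 to 1.49), Nupr1 (-2.22 to 0.45), Tgfbi (-2.83 to 0.35), Ccr7 (-0.56 to 2.72), Clec4e (-2.54 to 6.28), Hilpda (-0.18 to 3.93) and Src (-0.11 to 2.24). Abca1 ran from -0.16 to 0.45, and was -0.30 without pair 3. Pf4 ran from -0.37 to 0.15, and was 0.088 with upper-quartile factors and 0.27 without pair 2. These fits had no block, so leaving out 1 library numbered 3 left the level of that pair in a single group. Lcn2 measured 955 and 236 CPM in untreated and oxLDL sample 3 and at most 7.03 CPM in the other libraries. Ccl2 measured 611 and 100 CPM in sample 3 of these groups and at most 18.4 CPM in the others. For these genes the change of sign follows from the levels of pair 3. For the other genes the cause was not tested. In the simulation, whose setting favoured the block, a log2 fold of 1 was recovered in 53% of genes with the block. Changes of that size or smaller can thus be missed.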

Other observations

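The tests of cells of another type, of a lower share of macrophages, of the place of pair 2 between the other pairs, of scaling and of the splits for the gene count without the block were chosen after the result was seen, and the other tests before. The 3 numbered pairs differed from each other in 883 genes by edgeR's quasi-likelihood test of the pair term. The smallest adjusted p belonged to Lcn2, a siderophore-binding protein of innate defence, with 7.03, 3.82 and 955 CPM in untreated samples 1, 2 and 3 and 1.68, 0.935 and 236 CPM in the oxLDL samples. Cd38, an enzyme that consumes NAD, measured 5.32, 3.82 and 186 CPM untreated and 5.45, 5.07 and 181 CPM with oxLDL. Ccl2 measured 18.4, 18.0 and 611 CPM untreated and 3.97, 3.54 and 100 CPM with oxLDL, and the signalling scaffold Malt1 29.1, 31.2 and 357 CPM and 42.6, 57.0 and 701 CPM. Rgs18 ran the other way, with 82.6, 73.1 and 7.58 CPM untreated and 35.9, 28.3 and 2.89 CPM with oxLDL. Clec4e, the mycobacterial glycolipid receptor Mincle, measured 46.5, 29.0 and 3119 CPM untreated and 177, 192 and 8359 CPM with oxLDL, and it rose with oxLDL in the blocked fit (2.02 ± 0.32, adjusted p = 0.0421). Il6 and Il1a were below the count filter: Il6 had 8, 3 and 239 counts untreated and 1, 4 and 825 with oxLDL, and Il1a had 3, 1 and 241 and 4, 7 and 642.

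By list, the median level of NF-kB mediators relative to each gene's mean was 0.21, -0.27 and 1.64 in untreated samples 1, 2 and 3, and -1.25, -1.67 and 1.37 in the oxLDL samples. Alternative activation genes stood at 0.93, 1.32 and -2.21 untreated and 0.88, 0.49 and -0.85 with oxLDL, and cell cycle genes at 0.94, 1.14 and -0.82 and 0.34, -0.49 and -1.0004. Several genes nonetheless changed by a similar ratio in every pair: the log2 ratios of Lcn2 were -1.98, -1.88 and -2.02, and those of Ccl2 were -2.17, -2.30 and -2.60. Others did not: Nfkbiz had ratios of -4.50, -4.51 and 0.01 and Emr1, the gene of the macrophage marker F4/80, of -2.76, -3.86 and -0.31, and whether these differ between pairs was not tested. NRF2 genes stood at -0.998, -1.17 and -0.08 in untreated samples 1, 2 and 3 and at 0.66, 0.85 and 0.76 in the oxLDL samples.

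The first pattern is this difference between pairs, for which the sex of the mice is a candidate explanation. Xist, transcribed from the inactive X chromosome, measured 957, 505 and 0.341 CPM in untreated samples 1, 2 and 3 and 966, 346 and 0.0724 CPM in the oxLDL samples, while 4 Y-linked genes summed to 64.6, 228 and 230 CPM and 59.1, 221 and 265 CPM. Pairs 1 and 2 may thus hold RNA of both sexes and pair 3 of males, yet as the whole cause this is argued against by pair 2, whose median place on the way from pair 1 to pair 3 was 0.0612 over 878 genes that differ between pairs, against 0.558 for Xist and 0.875 for the Y-linked genes. GC content and gene length are argued against by a share of 0.931 of the genes kept after correction. Cells of another type stay open, as only 4 of 9 marker lists had at least 3 measured members. Their highest sum was 229 CPM (monocyte markers, pair 1), and the highest pair exceeded the lowest 3.05 times for dendritic cell, 2.44 times for monocyte, 1.96 times for osteoclast and 1.25 times for neutrophil markers. A partial effect of sex and a difference in culture or handling stay open. No group of the design separates the pairs, so no biological explanation from the design was tested.

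The second pattern is the lower level of interferon-stimulated genes with oxLDL. The choice among 4 scalings moved the list's median log2 difference only between -2.99 and -2.88. A scaling shifts all genes of a library nearly alike, so this comparison could hardly have come out otherwise. The median of all genes was 0.0015 to 0.119 under the same scalings, so the list was lower relative to the median gene under each of them. GC content and gene length are argued against by a median of -2.98 in the blocked fit after correction (SD 0.90 over 27 genes, and -2.99 before). An effect of oxLDL on a basal interferon response of the cultures is a hypothesis that may account for the pattern. It was found on the same data and was not tested.

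The third pattern is the lower level of the list of macrophage identity genes with oxLDL. Its median log2 fold change was -0.91 without the block and -0.82 with it, and 12 of 13 measured members were negative without it. A lower share of macrophages would raise the markers of other cell types. Their median log2 fold change with the block was -1.48 over 22 measured markers (quartiles -1.97 and -0.36), with 19 negative. Of the 22, 6 were monocyte and 6 neutrophil markers. The T cell, B cell, mast cell and megakaryocyte lists had 1 measured member each and the fibroblast list 0. The measured markers gave no sign of a rise, but for most lists too few were measured to decide, so a lower share stays open. A change of state within the macrophages may account for the pattern and was not tested.

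Other splits of the 6 samples were too few for a share under 0.05. Of 10 splits into 3 and 3, all 10 gave as many genes without the block in edgeR as the real one (real 0, highest other 0, with 1674 genes at an unadjusted p under 0.05 and 872 called by DESeq2 in the real split). For the lists 1 split of 10, the real one, gave 16 lists, and the other splits gave 5 to 14. The preset correlation thus passed several lists under every grouping of the samples. Among the 4 splits that part all 3 pairs, the real one alone gave 672 genes with the block (1 of 4), and the highest other gave 0.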
